A study of Mus musculus with 2 samples.

How the data were processed

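H3K27ac ChIP-seq was done on liver of mouse embryos at 11.5 days, as 1 group of 2 biological replicates, each a separate pool of embryos of both sexes (strain B6NCrl). Both replicates were used and none was left out. With 1 group there was nothing to pair and no group comparison, so the comparisons were between the replicates and between genes, regions and sequences within the tissue.

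The deposited files were 4 lists of peaks in mm10 coordinates: 1 per replicate, 1 called by the authors on the reads of both replicates together (the pooled list), and a replicated list, each entry of which was identical to an entry of the pooled list. The fold enrichment deposited with each peak is a ratio of ChIP over background, by the authors. The deposited p and q of each peak are given by the authors as −log10 values. The deposited summit is an offset in bp from the peak's start. The labels name a control experiment. The aligner, the peak caller and their versions were not given in the sources used here, nor were total read numbers. Because the replicated list keeps the pooled values, its folds are those of the pooled reads, and values per replicate were taken from the replicates' own lists and are given as mean ± SD over the 2 replicates. Coordinates are given counted from 1.

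Depth was read from the peaks, by a calculation devised after the files had been seen. Fold and p together gave the number of ChIP fragments at the summit and the background there, under an assumed formula. In it the fold was the scaled fragment number plus 1 over the background plus 1, and p was a Poisson tail. Only whole fragment numbers were tried, and the best one was kept for each peak. The scales, found by a search within preset ranges, were 1 for replicate 1, 0.896 for replicate 2 and 0.941 for the pooled list. With them the kept number gave back the deposited −log10 p within 0.01 for 100% of peaks. At a scale 3% higher it did so for 1.66%, 5.11% and 4.76%. The medians were 9, 12 and 16 fragments. The lowest background, without the scale, was 1.38, 1.46 and 2.88 fragments. No interval per peak was computed, and a weak peak that is missing from a list may have been too shallow to call rather than unacetylated.

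Peaks on chromosomes 1 to 19, X and Y were kept, 60497 of 60503 in replicate 1, 51832 of 51836 in replicate 2, 65698 of 65703 in the pooled list and 36127 of 36130 in the replicated list. Genes were the 21938 protein-coding genes of GENCODE M21 on these chromosomes. Peaks were shared when they overlapped by at least 50% of either peak. By that rule 27321 replicated peaks (75.6%) were shared with a peak in the list of both replicates, and the other 8806, with a median fold of 3.78 against 5.86, were not, so that rule applied to the deposited replicate lists did not give the replicated list. The rule the authors used is not stated in the sources used here.

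Overlap of the replicates was compared with 100 shuffles of the peaks within chromosomes (permutation, one-sided), and the share of replicated peaks at promoters (within 1 kb of a protein-coding TSS), exons, introns and intergenic sequence with 100 shuffles (permutation, two-sided). Spearman's rho was computed across shared peaks, with an interval from 200 resamples of the chromosomes. A gene was marked when a replicated peak lay within 1 kb of any of its TSSs, and each gene list was compared with all other protein-coding genes by Fisher's exact test, two-sided. Coverage was the sequence within 50 kb of a gene's 5′ end covered by peaks, those of neighbouring genes included. The median of each list was compared with 10000 random lists of the same size (permutation, two-sided). Peaks 12.5 kb or less apart were joined to domains, scored by the sum of fold times width, and called large past the point of slope 1 of the ranked scores. Lists were compared with large domains by Fisher's exact test, two-sided. For motifs, 500 bp at the summit of replicated peaks over 1 kb from any TSS were paired with 1 window 10 to 100 kb away that overlapped no peak and had a GC content within 2 percentage points, which 98.4% of 19722 peaks had, and 17 fixed motifs were compared by an exact McNemar test, two-sided. The p of the gene lists and motifs were adjusted by Benjamini-Hochberg over the 14 lists or 17 motifs, with a threshold of 0.05, and those of the shuffles were not adjusted.

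The tests, gene lists, motifs, loci and naming rule were fixed before the data were examined. The 14 lists were erythroid, globin, hepatoblast and fetal liver secreted proteins, hepatic transcription factors, postnatal hepatocyte metabolism, haematopoietic stem and progenitor, myeloid with macrophage and megakaryocyte, endothelial, mesenchyme with stellate and mesothelial, neural, heart and skeletal muscle, limb and posterior body, other endoderm, and widely expressed genes. They held 289 genes, of which Ahsp, of the globin list, was absent from the annotation. The lists were drawn up from general knowledge and not from these samples. The naming rule took, in each list, the 3 members with the largest coverage and up to 3 unmarked members in list order, the genes at the 12 highest-scoring domains, the genes nearest the 5 peaks of highest fold, and 7 loci. Genes outside it are named as chosen after their values were seen.

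Alternatives planned in advance were another overlap rule, stricter q, the pooled list, the list of each replicate alone, other promoter, coverage, motif and stitching windows, promoter peaks left out, domains scored by width alone and random genes of like gene density. Added after the files were seen were TSSs of all genes, a background without olfactory, vomeronasal and predicted genes, a gene's 5′ end in the domain, peaks found in both replicate lists, genes matched on promoter CpG content (1000 bp, 20 bins) and rotations of the gene order. Sequences of 50 bases that occur more than once in the genome were counted around list genes.

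The steps were tested on simulated data. Of 200 lists of 25 genes with a planted promoter difference 100% were called, and 4.5% of lists without one. Of 200 lists of 20 genes with planted coverage 94% were called, and 5.5% of lists without. In both simulations genes were drawn independently and calls used the unadjusted p. These rates therefore need not hold for neighbouring genes that count the same peaks, or for adjusted calls. Each simulation planted a single large increase, and the simulated coverage held no zeros. The rates do not show how often smaller increases, or decreases, would be called. The pass mark for planted coverage had been 95% and was lowered to 90% after the 94% was seen, with the simulation unchanged. Fragment numbers were recovered for 100% of 500 simulated peaks. These were made with the formula used for the recovery, and the scale was given, so neither the formula nor the search for the scale was tested. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, bedtools 2.31.1, samtools 1.23.1 and matplotlib 3.10.9 were used.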

Results

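H3K27ac, an acetylated form of histone H3 found at active promoters and enhancers, was mapped by ChIP-seq in the liver of mouse embryos at day 11.5 of gestation. At this stage blood-forming cells, most of them red cell precursors, share the liver with hepatoblasts, the precursors of hepatocytes and bile duct cells. The series held 1 group of 2 biological replicates. Each replicate was a separate pool of livers from embryos of both sexes of the B6NCrl strain, and the pool of replicate 1 came from 109 embryos. No other tissue, stage or histone mark was analysed here, so the comparisons below are between the replicates and between genes and regions of the same tissue.

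The authors' peak list of replicate 1 held 60503 peaks and that of replicate 2 held 51836. These peaks covered 27.4 and 28.9 Mb of the mm10 genome, or 1.01% and 1.06% of it. A list called on the reads of both replicates together held 65703 peaks, and the replicated list, a subset of the pooled one, held 36130 peaks over 31.5 Mb. Total read numbers were not given in the sources used here. The files showed depth only through the peaks. By the fragment numbers worked out from fold and p, a median of 9 ChIP fragments lay over a peak summit in replicate 1. It was 12 in replicate 2 and 16 in the pooled list.

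The replicates shared their strong peaks and differed in their weak ones. Of the peaks of replicate 1 on chromosomes 1 to 19, X and Y, 31704 (52.4%) shared at least 50% of either peak with a peak of replicate 2. In the other direction the share was 29105 peaks, or 56.2%. With 50% of both peaks required the shares were 33.7% and 39.3%. With both lists cut to peaks with a −log10 q of at least 5, 15844 and 20553 of them, they were 86.7% and 64.4%. Among the 10% of peaks with the smallest p given by the authors, 99.95% and 99.98% were shared, against 20.2% and 25.6% of the 10% with the largest. Shuffling the peaks within chromosomes gave 1.57% and 1.91%, and none of 100 shuffles reached the observed share (one-sided permutation p = 0.0099 for each replicate, the smallest that 100 shuffles can give).

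**Figure D1:**
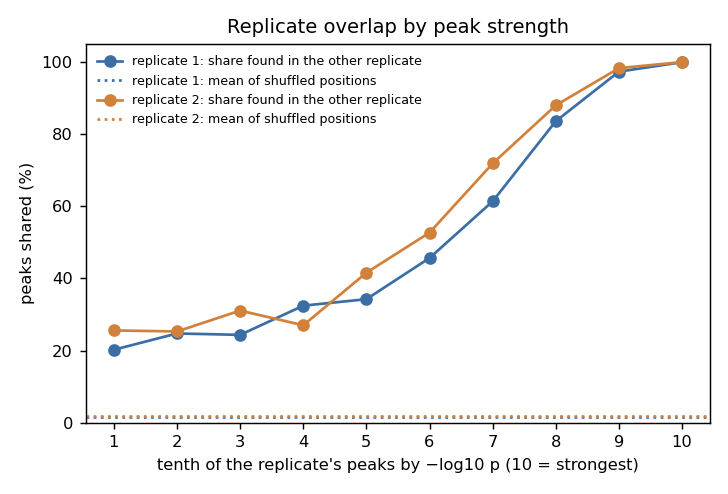
Share of each replicate's H3K27ac peaks that overlapped a peak of the other replicate (vertical axis, %), in 10 bins of equal size by the authors' p within that replicate's list (horizontal axis, weakest to strongest). Sharing stayed between 20.2% and 45.7% over the 6 weakest bins of replicate 1 and rose to 99.95% in its strongest bin.

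Peaks that were strong in one replicate were mostly strong in the other. Across 27359 pairs of shared peaks, the fold enrichments over background given by the peak caller had a Spearman rho of 0.714 (95% interval from resampling chromosomes, 0.706 to 0.724). Peaks are not independent replicates, so no p was computed. The fold in replicate 2 was the higher one in 71.8% of pairs, with a median ratio of 1.20. Peaks found in a single replicate were weak, narrow and mostly away from promoters. The 28793 peaks found only in replicate 1 had a median fold of 3.36 and a median width of 216 bp, and 18.8% lay at promoters, against 4.70, 439 bp and 46.8% for its shared peaks. The 22727 peaks found only in replicate 2 had a median fold of 3.87 and 23.3% lay at promoters, against 5.78 and 47.7% for its shared peaks.

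Promoters held fewer peaks than the rest of the genome but the taller and wider ones. In the replicated list, 14890 of 36127 peaks (41.2%) came within 1 kb of a transcription start site (TSS) of a protein-coding gene, 7.32 times the 5.63% found after shuffling. A further 32.6% lay in introns, 3.21% in exons and 23.0% between genes, against 34.7%, 2.71% and 56.9% after shuffling. Each share differed from the shuffled peaks with a two-sided permutation p of 0.0198, the smallest that 100 shuffles can give. The intron share turned above the shuffled level in the pooled list (39.2% against 35.1%) and in each replicate's own list. The exon share was not above it among peaks with a −log10 q of at least 5 (2.59% against 2.66%) or with promoters of 2.5 kb (2.14% against 2.17%). Among peaks found in both replicate lists the exon share was level with it (2.69% against 2.67%, two-sided permutation p = 0.871). Promoter peaks had a median fold of 6.64 and a median width of 776 bp, against 4.49 and 510 bp for the 21237 other peaks. In all, 10569 of 21938 protein-coding genes (48.2%) had a replicated peak within 1 kb of a TSS and are called marked below.

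Genes of the red cell lineage were marked at nearly every promoter and lay in long stretches of acetylated sequence. Of the 30 erythroid genes 29 were marked, in the replicated list and in each replicate's own list, against 48.1% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 1.77e-07 over 14 lists). The largest coverage in the list was at Zfpm1 (chromosome 8, 122282141 to 122337251), which encodes the GATA1 cofactor FOG1, with 51741 bp of replicated peaks within 50 kb of its 5′ end. Nfe2 and Gfi1b, which encode transcription factors of red cells and megakaryocytes, followed with 27910 bp and 25006 bp. In the replicates' own lists the promoter folds of these genes were 26.0 ± 2.29, 17.6 ± 5.44 and 16.8 ± 1.19 (SD, n = 2). Among members picked for mention after their values were seen, the promoter folds were 24.0 ± 6.68 for Klf1, an erythroid transcription factor, 21.1 ± 0.835 for Epor, the erythropoietin receptor, and 5.49 ± 0.559 for Alas2, the red cell enzyme that starts haem synthesis. The list had a median of 9960 bp, against 1661 bp in random lists of 30 genes (two-sided permutation test, adjusted p = 0.000933, raw p = 0.0002, the smallest that 10000 random lists can give). In the replicates' own lists the median was 8.89 ± 0.342 kb (SD, n = 2). With promoter peaks left out it was 3319.5 bp in the replicated list, and the call held. The unmarked member was Slc25a37 (chromosome 14, 69241848 to 69285112), the mitochondrial iron importer of red cell precursors, with 0 bp of replicated peaks. Of the 50-base sequences within 50 kb of its 5′ end, 81.0% occur elsewhere in the genome.

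The globin list, 9 globin genes and Nprl3, had the largest median coverage of the 14 lists. Of 10 members 9 were marked, all but Hbq1a (Fisher's exact test, two-sided, adjusted p = 0.013). The median was 35515.5 bp within 50 kb, against 1685 bp in random lists and 5708.75 bp in lists of like gene density, and 29 ± 3.14 kb in the replicates' own lists (SD, n = 2; two-sided permutation test, adjusted p = 0.000933, raw p = 0.0002). Nprl3, the neighbour of the α-globin genes whose introns hold their enhancers, had the largest coverage with 45255 bp, followed by the embryonic gene Hba-x with 42434 bp and Hba-a1 with 41901 bp. With promoter peaks left out the median was 16860 bp. The 10 genes lie in 2 clusters and count many of the same peaks, so they are not independent. Against rotations of the gene order, which keep neighbouring genes together, the coverage call held (permutation adjusted p = 0.00467, range over its alternatives 0.0007 to 0.00467). The promoter call did not (permutation adjusted p = 0.12), and it ended under 3 of its other alternatives (Fisher's exact test, adjusted p from 0.0701 to 0.0787). Over all 11 alternatives the adjusted p of the exact or permutation test ran from 0.000467 to 0.12.

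The hepatic programme was marked at its regulators and at most of its secreted products. 18 of 20 hepatic transcription factor genes were marked (Fisher's exact test, two-sided, adjusted p = 0.000516), and their median coverage was 6047 bp against 1672 bp in random lists (two-sided permutation test, adjusted p = 0.007). Gata4 with 16856 bp, Gata6 with 11443 bp and Hnf1a with 10225 bp had the most. Their promoter folds were 8.47 ± 0.156, 12.9 ± 2.23 and 4.72 ± 0.649 (SD, n = 2). Hnf4a and Nr1h4, the bile acid receptor gene, were not marked in the replicated list, although Hnf4a had 6673 bp of replicated peaks within 50 kb. In the own lists of replicates 1 and 2, 19 and 18 of the 20 genes were marked. Hnf4a, Nr1h4 or both therefore had a promoter peak in replicate 1. The coverage call ended with a window of 100 kb (permutation adjusted p = 0.107, range over its alternatives 0.0007 to 0.107).

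Of 28 genes for hepatoblast and fetal liver secreted proteins, 21 were marked (Fisher's exact test, two-sided, adjusted p = 0.0121). Dlk1, a hepatoblast surface protein, had the largest coverage with 19644 bp, then the apolipoprotein genes Apom with 15615 bp and Apoa2 with 11290 bp. Their promoter folds were 7.80 ± 2.70, 5.46 ± 0.584 and 8.35 ± 4.10 (SD, n = 2). Apoa4, Apoc3, Fetub and 4 others were not marked. The median coverage was 4384.5 bp against 1655.5 bp in random lists (two-sided permutation test, adjusted p = 0.0341). That call did not hold under 6 of its 10 alternatives (permutation adjusted p from 0.0514 to 0.119, and from 0.0103 to 0.119 over all 10), among them the list of replicate 1 alone with 3181 bp. The promoter call did not hold under 2 of 11 (Fisher's exact test, adjusted p = 0.0701 and 0.162, and from 0.000467 to 0.162 over all 11).

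Genes of mature hepatocyte metabolism were mostly unmarked. 4 of 26 had a promoter peak, less often than other genes (Fisher's exact test, two-sided, adjusted p = 0.0018). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, Cyp8b1 and Cyp2e1 were among the unmarked members, with 0, 0 and 366 bp of replicated peaks within 50 kb. The largest coverage was at Hpd with 18767 bp, Cyp1a2 with 11372 bp and Gls2 with 8790 bp. Only Gls2 of these was marked in the replicated list, and the window of Hpd takes in the acetylated region around Rhof and Setd1b described below. Median coverage was 409 bp and did not pass the test (permutation adjusted p = 0.134). Against genes of like promoter CpG content the promoter call ended (permutation adjusted p = 0.529, range over its alternatives 0.000162 to 0.529), since 22.0% of such genes were marked.

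Of 18 genes of haematopoietic stem and progenitor cells 14 were marked (Fisher's exact test, two-sided, adjusted p = 0.0206). Lyl1 with 35401 bp, Ikzf1 with 17527 bp and Runx1 with 13714 bp, all encoding transcription factors, had the largest coverage within 50 kb. Their promoter folds were 18.5 ± 2.43, 13.9 ± 0.315 and 11.6 ± 2.22 (SD, n = 2). Coverage counts peaks of neighbouring genes too, and the large domain over Lyl1 also overlapped other genes. Cd34, Flt3 and Hoxa9 were among the 4 that were not marked. That call ended under 7 of its 11 alternatives, among them the list of replicate 1 alone, where 12 of 18 were marked (Fisher's exact test, adjusted p = 0.303, range over its alternatives 0.022 to 0.54). The median coverage of 3678 bp did not pass (permutation adjusted p = 0.149), although it did against random genes of like gene density and with promoter peaks left out (permutation adjusted p = 0.00728 and 0.028, range over its alternatives 0.00728 to 0.581).

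For 20 genes of myeloid cells, macrophages and megakaryocytes the promoters did not differ from other genes, with 12 marked (Fisher's exact test, two-sided, adjusted p = 0.4). Their median coverage of 5510 bp was higher than in random lists (two-sided permutation test, adjusted p = 0.0179). It was largest at Elane with 21287 bp, Cd68 with 16623 bp and the platelet receptor gene Gp9 with 16415 bp. These values count peaks of neighbouring genes too. Elane, which encodes neutrophil elastase, was itself unmarked, as were Adgre1, Lyz2 and Ptprc. The coverage call ended with a window of 10 kb (870.5 bp), with peaks found in both replicate lists (4228 bp) and in the list of replicate 1 alone (4015.5 bp). In these 3 the permutation adjusted p was 0.702, 0.0599 and 0.0504, and over all 10 alternatives it ran from 0.00187 to 0.702. Against genes of like promoter CpG content, of which 24.0% were marked, the promoter difference passed (permutation adjusted p = 0.0007, range over its alternatives 0.0007 to 1).

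Supporting cells of the liver showed no list-wide enrichment. Of 18 endothelial genes 5 were marked (Fisher's exact test, two-sided, adjusted p = 0.117), with Eng at 19595 bp, Nr2f2 at 17077 bp and the unmarked Stab1 at 10567 bp of coverage. Cdh5, Tek and Tie1, which encode endothelial adhesion and receptor proteins, were unmarked. In the list of replicate 1 alone 10 of 18 were marked, above the share of other genes, and in that of replicate 2 alone 7 were. Counting the 5′ end only, or leaving olfactory, vomeronasal and predicted genes out of the comparison, the list was marked less often (exact test, adjusted p = 0.0247 and 0.0462, range over its alternatives 0.0247 to 0.818). Of 20 genes of mesenchyme, stellate and mesothelial cells 11 were marked (Fisher's exact test, two-sided, adjusted p = 0.656). Hand2 with 10174 bp, Col1a1 with 6541 bp and Pdgfrb with 6057 bp had the largest coverage, and Des, Col1a2 and Acta2 were unmarked in the replicated list. Median coverage was 1198.5 bp for endothelial and 1501.5 bp for mesenchymal genes, neither past the test (permutation adjusted p = 0.667 and 0.861).

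Genes of other tissues were rarely marked. None of 22 neural genes had a replicated peak within 1 kb of a TSS (Fisher's exact test, two-sided, adjusted p = 4.36e-06), including Neurod1, Neurod2 and Neurog1, and the largest coverage was 5149 bp near Tubb3. 2 of 19 genes of lung, pancreas and gut were marked (adjusted p of the same exact test 0.00194), with Nkx2-1, Sftpc and Sftpb unmarked. 3 of 18 genes of the limb and posterior body were marked (exact test, adjusted p = 0.0128), with Hoxa11, Hoxa13 and Hoxd10 unmarked. 3 of 20 heart and skeletal muscle genes were marked (exact test, adjusted p = 0.00578), with Nkx2-5, Tnnt2 and Myh6 unmarked. In the list of replicate 2 alone 1 neural, 1 lung, pancreas and gut and 2 limb genes were marked, and these calls held. The heart and muscle call ended against genes of like promoter CpG content (permutation adjusted p = 0.0748, range over its alternatives 0.000745 to 0.0748). Median coverage was 0 bp in the first 3 of these lists and 1018.5 bp for heart and muscle, none past the test (permutation adjusted p = 0.0844, 0.137, 0.106 and 0.542). A median of 0 bp is the lowest possible. Random lists reached it so often that the raw permutation p was 0.0982 for other endoderm and 0.0608 for limb. For those lists this test could therefore not call lower coverage, and its outcome says nothing against it. The neural list was lower in the pooled list, with a window of 100 kb and in replicate 1 alone (permutation adjusted p from 0.0268 to 0.0364, range over its alternatives 0.0268 to 1), and the limb list against genes of like gene density (permutation adjusted p = 0.044, range over its alternatives 0.044 to 1).

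Of 20 widely expressed genes 19 were marked, all but Psmb2 (Fisher's exact test, two-sided, adjusted p = 5.63e-05), and the median coverage was 11174.5 bp (two-sided permutation test, adjusted p = 0.000933, raw p = 0.0002). With promoter peaks left out the median was 2100 bp, and the call held. The largest coverage was at the ribosomal protein genes Rplp0 with 26129 bp and Rpl13a with 23831 bp and at the elongation factor gene Eef2 with 22312 bp. Hmbs, an enzyme of haem synthesis, belongs to this list and to the erythroid one.

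**Figure D2:**
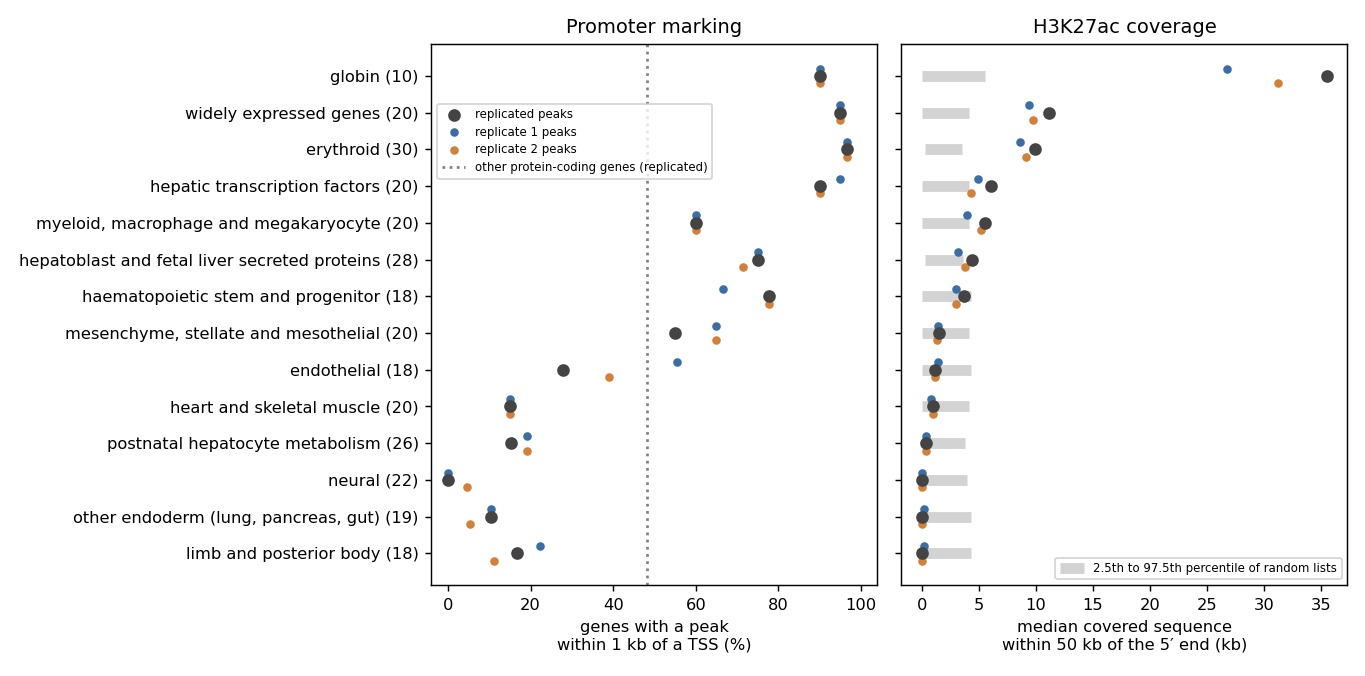
Left, share of each gene list (number of members in brackets) with an H3K27ac peak within 1 kb of a TSS (%), in the replicated list and in the list of each replicate; the dotted line marks the share of other protein-coding genes. Right, median sequence covered by peaks within 50 kb of the 5′ end (kb), with grey bars for the central 95% of 10000 random lists; the erythroid, globin, hepatoblast, hepatic transcription factor, myeloid and widely expressed lists lie above the grey bars and the neural list below, and no neural gene was marked in the replicated list.

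Between the 3′ end of Nprl3 and that of Hbq1a (chromosome 11, 32225628 to 32300873, mm10), 38 replicated peaks covered 44.0 kb, or 58.4% of the interval. In the replicates' own lists the covered length was 36.2 ± 3.32 kb (SD, n = 2). The strongest peak, at 32266655 to 32270114, spanned the Nprl3 promoter with a fold of 21.1 in the pooled reads. A peak in a Nprl3 intron at 32241267 to 32245766 had a fold of 19.5. In the replicates' own lists these folds were 18.1 ± 2.28 and 14.4 ± 1.66 (SD, n = 2). A peak of 4118 bp ended just upstream of the Hba-a1 start, at 32279344 to 32283461, with a fold of 9.82. The strongest peak at the embryonic gene Hba-x had a fold of 5.47. Of the 50-base sequences within 1 kb of the 5′ ends of Hba-a1 and Hba-a2, 69.1% and 74.6% occur elsewhere in the genome, so their values are uncertain.

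**Figure D3:**
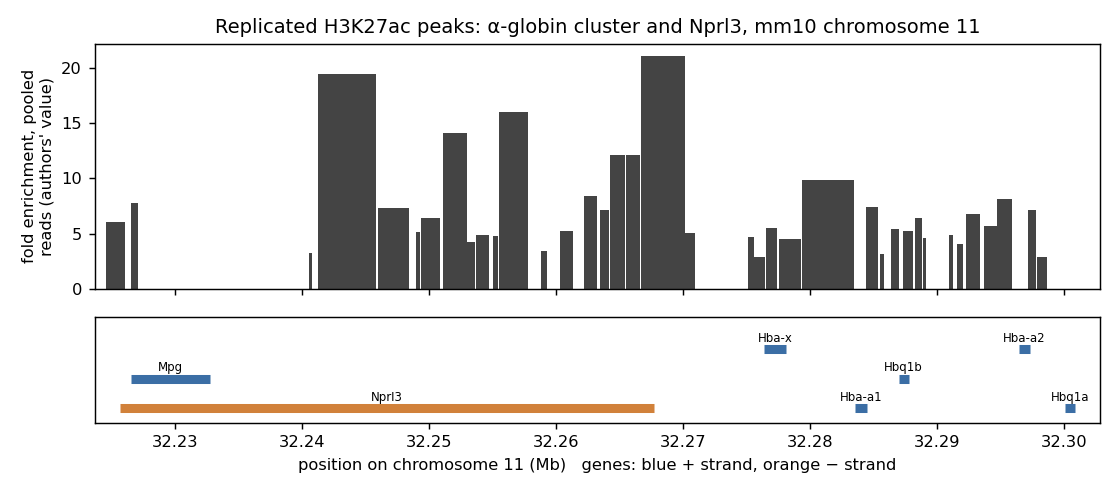
Replicated H3K27ac peaks at the α-globin cluster and Nprl3 (mm10 chromosome 11, position in Mb), each drawn at its width with the authors' fold enrichment in the pooled reads as its height. Genes are drawn below by strand; the 2 tallest peaks, with folds of 21.1 and 19.5, lie at the Nprl3 promoter and in a Nprl3 intron.

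In the β-globin region the strongest peaks lay beyond the genes. From Hbb-bt to 70 kb past Hbb-y (chromosome 7, 103812524 to 103923216), 39 replicated peaks covered 28.0 kb, or 25.3%, and 22.1 ± 0.677 kb in the replicates' own lists (SD, n = 2). The highest folds in the pooled reads were 21.2 at 103869409 to 103871024 and 20.8 at 103864526 to 103866533, with 15.9 ± 1.79 and 16.9 ± 2.51 in the replicates' own lists (SD, n = 2), both intergenic and between Hbb-y and Olfr66, where the locus control region of these genes lies. At the genes themselves the peak over the start of the adult gene Hbb-bt had a fold of 11.4, that over the start of the other adult gene, Hbb-bs, 4.49, that over the start of the embryonic gene Hbb-bh1 6.13, and that inside 1 kb of the embryonic Hbb-y start 3.30. Of the 50-base sequences within 1 kb of the 5′ ends of Hbb-bt and Hbb-bs, 40.8% and 34% occur elsewhere.

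**Figure D4:**
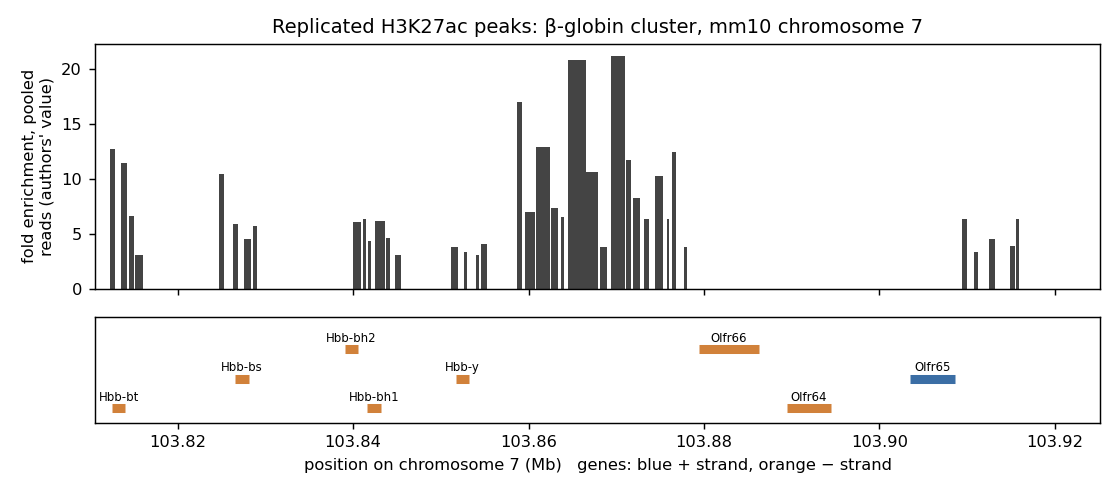
Replicated H3K27ac peaks at the β-globin cluster and 70 kb beyond Hbb-y (mm10 chromosome 7, position in Mb), each drawn at its width with the authors' fold enrichment in the pooled reads as its height. Genes are drawn below by strand; the tallest peaks, with folds of 21.2 and 20.8, lie between Hbb-y and Olfr66.

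Regulators of blood formation carried strong peaks both at and away from their promoters. At Tal1 with 60 kb downstream (chromosome 4, 115056426 to 115131755), 10 replicated peaks covered 17.7 kb. The promoter peak of 7001 bp had a fold of 23.3, with 19.2 ± 3.64 in the replicates' own lists. A peak of 4301 bp at 115093104 to 115097404, which ran from the 3′ end of the neighbouring gene Pdzk1ip1 into intergenic sequence, reached 24.5, with 17.6 ± 1.77 (SD, n = 2). Around Gata1 with 10 kb each side (chromosome X, 7949260 to 7988071), 7 peaks covered 6.83 kb, and the highest, with a fold of 11.2, lay in an intron. From Myb to Hbs1l, both genes included (chromosome 10, 21124935 to 21368898), 17 peaks covered 14.1 kb. In the pooled reads an intergenic peak 35593 bp from the Myb start had a fold of 10.003 and the Myb promoter peak one of 9.05, with 8.28 ± 2.71 and 6.45 ± 0.426 in the replicates' own lists (SD, n = 2). The highest peak of each replicate was another one, with a fold of 10.8 at 21241454 to 21243302 in replicate 1 and 12.3 at 21220827 to 21222279 in replicate 2.

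From Alb to Afp (chromosome 5, 90460897 to 90508907), which encode albumin and α-fetoprotein, 5 replicated peaks covered 3.47 kb, or 7.22% of the interval. In the pooled reads an intergenic peak 4406 bp upstream of Afp had a fold of 4.72 and the peak at the Afp promoter one of 3.77. In the replicates' own lists they had 3.88 and 3.87 (replicate 1) and 4.31 and 6.49 (replicate 2), or 4.09 ± 0.302 and 5.18 ± 1.85 (SD, n = 2). The peak at the Alb promoter had 4.33 in the pooled reads and 5.04 in replicate 1, and no peak was paired with it in replicate 2. The imprinted Igf2 to H19 interval with 30 kb downstream (chromosome 7, 142545529 to 142666816) held 23 peaks over 33.5 kb, or 27.6%. The strongest, with a fold of 17.0, spanned H19, and the peak at an Igf2 promoter had a fold of 13.5, with 10.02 ± 1.09 in the replicates' own lists (SD, n = 2).

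Joining neighbouring replicated peaks gave 14128 domains, of which 776 were large by the slope of their ranked scores. These 5.49% of domains held 39.5% of the summed score (fold times width) and had a median span of 25.4 kb. The top domain covered Zfpm1 (chromosome 8, 122273734 to 122350281), with 55.9 kb of peaks and 53.5 ± 0.262 kb in the replicates' own lists (SD, n = 2). Histone gene clusters ranked 2, 6 and 10, on chromosome 13 at 23498947 to 23596607 and 23723882 to 23769186 and on chromosome 3 at 96218589 to 96278583. The fourth (chromosome 11, 87689104 to 87760457) held Rnf43, Supt4a and the blood cell microRNA gene Mir142, and the fifth (chromosome 11, 78031285 to 78194981) held Traf4, Rab34 and the erythroid microRNA genes Mir144 and Mir451a. Others in the top 12 overlapped Polr2e, Gpx4 and Cirbp on chromosome 10, Zmynd8 and Nol4l on chromosome 2, Gse1 on chromosome 8, and Rhof with Setd1b and Actb with Fbxl18 on chromosome 5. The α-globin domain ranked 19.

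Large domains overlapped 19 of 30 erythroid genes, 9 of the 10 members of the globin list and 11 of 20 widely expressed genes, against 7.47% to 7.51% of other genes (Fisher's exact test, two-sided, adjusted p = 1.46e-13, 5.06e-09 and 1.81e-07). The members of the globin list again count as 2 clusters. Among the other lists, 4 of 18 stem and progenitor genes, 2 each of the hepatic transcription factor, myeloid and endothelial genes and 1 hepatoblast gene, Dlk1, lay in large domains. None of the postnatal hepatocyte, mesenchyme, neural, heart and muscle, limb or other endoderm genes did, and none of these 11 further lists passed (exact test, adjusted p from 0.147 to 0.72). With peaks within 2.5 kb of a TSS left out before joining, 488 domains were large and held no member of the globin or widely expressed list (exact test, adjusted p = 1 for both, ranges over their alternatives 3.98e-10 to 1 and 3.04e-11 to 1). They held 26.7% of the erythroid genes, whose call held. Without joining, 1713 single peaks were large, and they overlapped 1 of the 10 members of the globin list (exact test, adjusted p = 0.644) and 5 of the 18 stem and progenitor genes (exact test, adjusted p = 0.0463, range over its alternatives 0.0463 to 0.64).

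Of the 5 replicated peaks with the highest fold in the pooled reads, 3 lay at promoters and none at an erythroid, globin or hepatic list gene. The highest fold, 67.1, was at 123134234 to 123140612 on chromosome 5, 1542 bp from the Rhof start and over the non-coding gene AI480526, with 52.6 ± 0.394 in the replicates' own lists (SD, n = 2). It was followed by the promoters of Actb at 142904585 to 142910681 on chromosome 5 with 63.2, and Arid1a at 133751817 to 133757897 on chromosome 4 with 57.4. A peak between protein-coding genes, 4493 bp from Sirt4 at 115489218 to 115490495 on chromosome 5, reached 56.7. It lay over the non-coding genes Gm24265 and Gm24407. The promoter of Sp3 at 72978279 to 72981290 on chromosome 2 reached 55.3. In the replicates' own lists the folds of these 4 were 49.9 ± 12.4, 41.0 ± 5.08, 41.0 ± 3.31 and 43.4 ± 8.02 (SD, n = 2).

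Motifs assigned here to red cell transcription factors were more frequent in distal peaks than in matched sequence. Only sequence patterns were counted, so which factors bind them was not tested. In 19406 windows of 500 bp at the summits of replicated peaks over 1 kb from any TSS, each paired with an unmarked window of like GC content, the NFE2 motif was found in 1.08% against 0.5%, a ratio of 2.15 (exact McNemar test, two-sided, adjusted p = 3.27e-10 over 17 motifs). The ratio was 3.66 among peaks with a −log10 q of at least 5 and 1.61 in replicate 1 alone. The TAL1-GATA composite motif was found in 17.1% against 11.6%, a ratio of 1.47 (exact McNemar test, adjusted p = 2.1e-53). The GATA motif, which lies within the composite pattern, was in 59.7% against 52.6%, a ratio of 1.13. The KLF motif was in 21.1% against 19.1% (adjusted p of the same exact test 1.23e-45 for GATA and 8.38e-07 for KLF). The AP-1 motif, which lies within the NFE2 pattern, had a ratio of 1.17, and the PU.1 motif of myeloid cells one of 1.34 (adjusted p of the exact test 3.2e-07 and 1.46e-08).

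Motifs of hepatic factors were also more frequent. The FOXA motif had a ratio of 1.21, HNF4 one of 1.27 and CEBP one of 1.68 (exact McNemar test, two-sided, adjusted p = 1.44e-11, 1.03e-05 and 0.0318). The CEBP pattern contains a CpG, as does the ETS pattern below, and the paired windows were matched on GC content but not on CpG. MEF2, fixed as a motif of other tissues, was higher as well, at 1.45 (exact test, adjusted p = 0.0033). The CEBP and MEF2 calls ended in the peaks found in both replicate lists (exact test, adjusted p = 0.258 and 0.663, ranges over their alternatives 3.77e-07 to 0.258 and 3.16e-12 to 0.663). NEUROD, also fixed as a motif of other tissues, was less frequent than in the paired windows, with a ratio of 0.897 (exact test, adjusted p = 0.000127). Whether its short pattern is particular to neural factors was not tested. ETS (ratio 1.25), RUNX (19.9% against 19.3%), HNF1 (2.20, from 11 against 5 windows), CTCF (0.901), POU (0.892) and RFX (1.44) did not pass (exact test, adjusted p from 0.112 to 0.523). ETS passed in all 5 of its alternatives (exact test, adjusted p from 0.000161 to 0.0292). HNF1 passed with windows of 1000 bp and in replicate 1 alone (exact test, adjusted p = 0.00014 and 0.0074, range over its alternatives 0.00014 to 0.302). POU was lower in each replicate's own list (exact test, adjusted p from 0.00344 to 0.0461, range over its alternatives 0.00344 to 0.928). RUNX passed with windows of 1000 bp (exact test, adjusted p = 0.0114, range over its alternatives 0.0114 to 1). The direction of CTCF turned with windows of 1000 bp (ratio 1.1), and that of RFX in 4 of 5 alternatives (0.600 to 0.833).

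**Figure D5:**
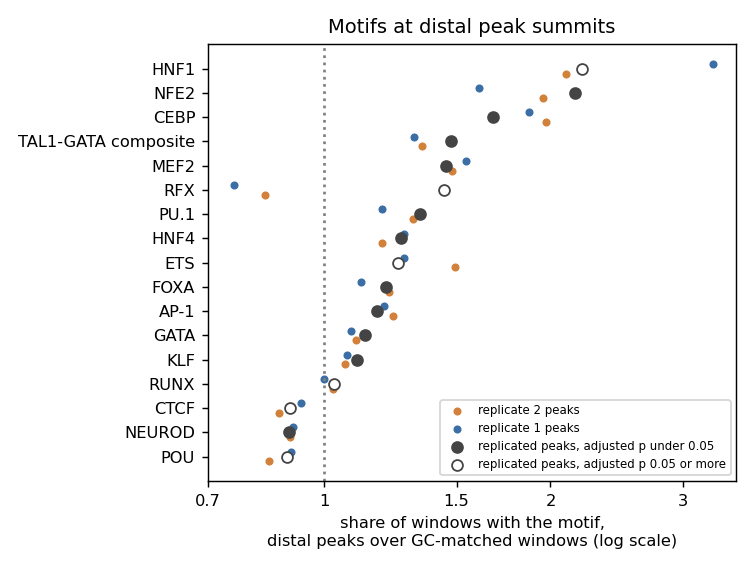
Ratio of the share of 500-bp windows with each motif, at distal peak summits over paired windows of like GC content outside peaks (log scale; dotted line, ratio of 1). Large circles show the replicated peaks, filled where the adjusted p was under 0.05, and small circles the peaks of each replicate; the TAL1-GATA composite lies at 1.47 and NEUROD at 0.897, while RFX lies above 1 in the replicated peaks and below it in each replicate.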

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

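The alternatives with peaks found in both replicate lists, the smaller background, CpG matching, rotations, all TSSs and the 5′ end in a domain were chosen after the data were seen; the others were planned. Of 522 alternative values for 66 results, 444 kept the direction and side of the threshold (or the size, where there was no test) and 78 did not; the cause was not tested. Erythroid genes kept their promoter, coverage and domain calls in every alternative run, as did the share of replicated peaks at promoters. The overlap of the replicates stayed above the shuffled level, but its size moved. It ran from 33.7% of replicate 1 and 39.3% of replicate 2 (50% of both peaks) to 86.7% and 64.4% (−log10 q of at least 5 in both lists). The weakest peaks had few fragments, so depth may limit them, which was not tested.

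Rho was 0.775 with 50% of both peaks and 0.753 on −log10 p. Promoter shares that lost their call were, for stem and progenitor genes, 77.8% (pooled list, smaller background, CpG matching), 61.1% (−log10 q of at least 5) and 55.6% (peaks found in both lists, 5′ end only); for the globin list, 80% (−log10 q of at least 5, promoters of 0.5 kb) and 90% (smaller background, rotations); for hepatoblast genes, 60.7% (−log10 q of at least 5) and 75% (smaller background); and with CpG matching 15.4% of postnatal hepatocyte and 15% of heart and muscle genes. Calls appeared for endothelial genes at 16.7% (5′ end only) and 27.8% (smaller background) and for myeloid genes at 60% (CpG matching). Mesenchymal genes, at 55%, turned below the smaller background. With 1 replicate left out, stem and progenitor genes were at 66.7% to 77.8% and endothelial genes at 38.9% to 55.6%.

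Coverage calls ended for hepatoblast genes at 3565.5 bp (−log10 q of at least 5), 3574 bp (peaks found in both lists), 7003.5 bp (100 kb) and 4384.5 bp (gene density, rotations), for hepatic transcription factors at 8237.5 bp (100 kb), and for myeloid genes at 4228 bp (peaks found in both lists) and 870.5 bp (10 kb). Calls appeared for neural genes at 0 bp (pooled list) and 358.5 bp (100 kb), for stem and progenitor genes at 1511.5 bp (promoter peaks left out) and 3678 bp (gene density), and for limb genes at 0 bp (gene density). The direction turned, without a call, for endothelial genes at 2231.5 bp (pooled list), 580 bp (promoter peaks left out) and 1198.5 bp (gene density), and for mesenchymal genes at 509.5 bp (10 kb), 304 bp (promoter peaks left out) and 1501.5 bp (gene density). With 1 replicate left out the medians were 3181 to 3828 bp for hepatoblast, 4015.5 to 5201.5 bp for myeloid and 0 to 0 bp for neural genes.

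Large domains numbered 1713 without joining and 488 without peaks near TSSs. Without joining, 10% of globin list, 27.8% of stem and progenitor and 5.56% of endothelial genes overlapped them. Without peaks near TSSs it was 0% of globin list, myeloid, endothelial and widely expressed genes. Joining over 5 kb gave 7.14% of hepatoblast, 5% of myeloid and 5.56% of endothelial genes, width alone 14.3% of hepatoblast genes, and peaks found in both lists 5% of hepatic transcription factor and 5.56% of endothelial genes. With 1 replicate left out hepatoblast genes were at 10.7% to 14.3%.

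Motif ratios with windows of 1000 bp were 1.3 for ETS, 1.04 for RUNX, 3.70 for HNF1 and 1.1 for CTCF. With a −log10 q of at least 5 they were 1.68 for ETS and 0.625 for RFX, and with peaks found in both lists 1.45 for ETS, 1.43 for CEBP, 1.08 for MEF2 and 0.600 for RFX. With 1 replicate left out they were 1.28 to 1.49 for ETS, 2.10 to 3.29 for HNF1, 0.845 to 0.903 for POU and 0.759 to 0.833 for RFX.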

Other observations

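The tests of the scale, of depth and of the 4 single lists below were chosen after the result was seen, and the others before. Several list members outside the naming rule had high promoter folds and were chosen after their values were seen. These were Etv6, a haematopoietic transcription factor, at 20.6 ± 6.01, Glul, glutamine synthetase, at 16.7 ± 0.453, Vwf, von Willebrand factor of megakaryocytes and endothelium, at 15.3 ± 0.0811, and Xbp1, a regulator of secretory cells, at 15.2 ± 0.0784 (SD, n = 2). Of the 3 marked heart and muscle genes, Tbx5, Myl4 and Mef2c, Myl4, an atrial and embryonic myosin light chain, had 13.0 ± 1.18. The marked limb genes were Sox9, Col2a1 and Hand1, and the marked other endoderm genes Barx1 and Satb2.

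Folds at shared peaks were higher in replicate 2. The scale worked out from the deposited fold and p was 1 for replicate 1 and 0.896 for replicate 2. Under the assumed formula that scale lowers the folds of replicate 2. Leaving it out could therefore only raise the median ratio, from 1.20 to 1.24 (1.24 to 1.25), and that test was void. The ratio of fragments at paired summits was 1.3 times that of the lowest backgrounds, more than depth alone would give. A larger share of erythroid cells in the second pool would leave widely expressed genes level if erythroid and other cells acetylate them alike. That assumption was not tested. The median promoter ratio of the widely expressed genes was 1.35 (1.20 to 1.53). Under the assumption, this ratio argues against such a share as the whole cause. All 10185 genes marked in both replicates had a median ratio of 1.25, so this test could not show a smaller part beside a general shift. The erythroid list, at 1.26 (1.11 to 1.56), did not differ from those genes (two-sided permutation test, adjusted p = 0.916). A difference in ChIP yield could be involved and was not tested, nor was a biological difference between the pools.

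Promoters rich in CpG carry H3K27ac in many tissues, so CpG content could produce differences between lists. Of 6 lists marked more often than other genes 5 were still called against genes of like CpG content, and of 5 marked less often 3 were, which argues against CpG content as the cause for those. For postnatal hepatocyte genes 20.2% of the distance to the chance level stayed, so CpG content may account for most of that difference. For stem and progenitor genes 68.3% and for heart and muscle genes 61.2% stayed while the calls ended, and the lists of 18 and 20 genes cannot decide. Neighbouring list genes that count the same peaks could inflate coverage, but 5 of 6 lists were still called against rotations of the gene order; for hepatoblast genes 100.6% of the distance stayed while the call ended through the wider spread of the rotations (central 95% from 0 to 4450.6 bp), which leaves that list open.

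Slc25a37, the unmarked erythroid gene, may be unmarked because reads there could not be placed. Of the 50-base sequences within 50 kb of its 5′ end 81.0% occur elsewhere in the genome, against a median of 4.87% over the erythroid list, and 100% within 1 kb. Whether the authors removed such reads is not given in the sources used here, and no biological explanation was tested.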
